A study of Mus musculus with 6 samples.

How the data were processed

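The series holds 6 two-colour Agilent whole mouse genome arrays of ventral prostate RNA from FVB mice. On every array the green dye (Cy3) carried RNA of young wild type mice, 2.5 months old. The red dye (Cy5) carried RNA of the fl26 line, transgenic for full-length 15-LOX2, of the svb9 line, transgenic for its splice variant b, both at 2.5 months, or of old wild type mice at 15 months. Each of these 3 groups has 2 arrays. The sample labels describe pools of ventral prostates from 3 mice, whereas the design text describes combined lobes of 6 mice, and the files do not settle which holds. Whether arrays shared a young wild type pool is not stated. The dyes were never swapped, so dye and group cannot be separated in a comparison with young wild type, whereas dye cancels between red groups.

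Spot intensities were read from the scans with Agilent Feature Extraction A.7.5.1, per the file headers, and the deposited files give the mean intensity of each spot and the median intensity of its background in each channel, without normalization. The deposited log10 ratios of red over green were background-subtracted, spatially detrended and dye-normalized (linear and LOWESS) by the same software, per the file headers. The deposited series table holds those log10 ratios rounded. They also flag, for each spot and channel, signal well above background, saturation and outliers, per the file headers.

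The values reported were computed from the spot intensities in R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8). Control spots (2256 of 43790) and spots flagged as outliers were left out, and saturated spots were kept. Background was corrected by the normexp method with an offset of 50, each array was normalized by loess, and replicate spots were averaged, giving log2 ratios for 41174 probes. The tested set was 27860 probes well above background in the same channel on both arrays of at least 1 group. Of these, 26016 had values on all 6 arrays and 1844 on fewer. Gene names came from the reference gene table (GRCm38.p6), used for names and for which genes are neighbours only. It named 20716 probes through the systematic name and 92 through a RefSeq accession, and 20366 kept the name in the file. A usable gene symbol was available for 25519 probes.

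A linear model with 3 group means was fitted to the log2 ratios of all 6 arrays with limma, with moderated variances. Each group mean was tested against 0, and the groups were tested against each other, 2-sided, with Benjamini-Hochberg adjustment over the probes and a threshold of 0.05. A test against 0 leaves out the spread of the young wild type pools themselves unless those differ between arrays. Standard errors and adjusted p values of single genes come from limma. They rest on a spread pooled over all 6 arrays and moderated across probes, not on the 2 arrays of a group alone. Arrays were extracted on 3 dates, which are used as batches because no scan date is given. The first date holds array 1 of fl26 and of svb9. The second holds fl26 array 2 and old array 1, and the third holds svb9 array 2 and old array 2. Groups share the replicate numbers 1 and 2, which the labels do not describe as a pairing. Deviations from the group means of same-numbered arrays correlated with r = 0.61 for fl26 and svb9, 0.33 for fl26 and old wild type and 0.17 for svb9 and old wild type, so a fit with the replicate number as a block is given where it changes a call. Placing that fit beside the results was decided after the calls had been seen, on these correlations and not on the calls. With 2 arrays per group, both arrays of a group give the same correlation. A fit with the date as a term was run for every comparison, and within-date differences between groups are given beside the list results. With 6 arrays, 3 groups and 3 dates, that fit leaves little information per probe to estimate the spread. Its calls rest largely on variances moderated across probes and assume that a date shifts all groups alike.

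Before the data were examined, 31 lists of pathway genes and cell type markers were fixed, as were the tests, the alternatives and the rule for named genes. Lists were tested with camera on limma's statistics with a preset correlation of 0.01, on 20070 genes with values on all arrays, each represented by its probe of highest mean intensity, and adjusted over the 31 lists. Camera with an estimated correlation and fry were run beside it. The rule named 14 genes in each comparison with young wild type, where measured, and 2 of these are not reported here. It also named up to 8 genes with the largest rise and up to 8 with the largest fall among those past the threshold, with the same sign on both arrays and signal well above background. Where no gene passed, it named the 5 genes with the smallest unadjusted p. For each list past the threshold in a comparison with young wild type or of fl26 with svb9, it named up to 4 members with the largest log2 ratio.

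The model was tested on simulated data for fl26 against young wild type with 27860 probes. It recovered 21 of 50 probes changed by 0.5 on the log2 scale, 48 of 50 changed by 1, 50 of 50 changed by 2 and 50 of 50 changed by 3. It called 9 of 27660 unchanged probes. The simulated noise was independent between arrays and drawn with the moderated variances, whereas deviations of same-numbered arrays correlated in the data. Recovery in the data may thus be lower. There, 35 probes were at least 2-fold on both fl26 arrays, and 14 probes were called. The list test gave an adjusted p of 5.43e-45 for a list raised by 0.5 and called 0 others. The simulated genes varied independently, so this cannot show how the list test behaves where genes of a list vary together.

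Alternatives covered background correction, the deposited log ratios, median centring, quantile normalization between arrays, the probe filter, flagged spots, the variance model, array weights, 1 value per gene, a test against a 1.5-fold change, blocks for date and for replicate number, a separate-channel fit, and leaving out each array in turn. Treating saturated spots as missing was added after seeing the data. No array was left out of the values reported. The number of arrays per group, 2, limits the precision.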

Results

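Gene expression in the ventral prostate was measured in 2 transgenic mouse lines and in old mice, each against young wild type mice on the same array. The fl26 line carries full-length 15-LOX2, a lipoxygenase that oxidizes arachidonic acid, and the svb9 line carries its splice variant b. The 3 groups (fl26, svb9 and old wild type) have 2 arrays each, and values are log2 ratios of the group over young wild type.

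Signal differed between arrays. In the red channel, 27151 probes of fl26 array 1 and 27833 of svb9 array 1 were well above background, against 17623 of fl26 array 2 and 14620 of svb9 array 2. Old array 1 had 3219 such probes and old array 2 had 13600. In the green channel, which held young wild type RNA, the number lay between 24837 and 30382. The 10 brightest probes took 28% of the red signal on old array 1, against 1.71% to 10.1% on the other arrays. On both arrays of a group, red signal stood well above background for 17618 tested probes in fl26, 14610 in svb9 and 3205 in old wild type, so most genes of the old group were measured near background.

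The first comparison asked which genes differ between the fl26 line and young wild type. Rb1cc1, which encodes a component of the complex that starts autophagy, rose 4.79-fold, with a log2 ratio of 2.26 ± 0.13 (limma standard error, n = 2). This error pools the spread of all 6 arrays, and the 2 fl26 arrays lay at 2.51 and 2.01. Tph1, which encodes the enzyme of the first step of serotonin synthesis, rose 2.98-fold (log2 1.57 ± 0.10), and Tmem94, a membrane protein gene, rose 2.09-fold (log2 1.06 ± 0.09). Psmc3ip, a gene of meiotic recombination, fell, with a log2 ratio of -2.14 ± 0.17. Sh2d4a, an adaptor with an SH2 domain, had -1.74 ± 0.11, and Creb3l4, a transcription factor bound to the endoplasmic reticulum, had -1.62 ± 0.13. Nrcam, a cell adhesion gene, had -1.20 ± 0.10, with red signal well above background on 1 array, and Ubash3b, a phosphatase gene, had -0.79 ± 0.07. All 8 genes had the same sign on both arrays, as the rule required, with adjusted p between 0.0190 for Rb1cc1 and 0.0486 for Ubash3b.

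Other probes of these genes gave smaller values. The 4 other probes of Rb1cc1 had log2 ratios from 0.31 to 1.83, the second probe of Psmc3ip had -1.20 and that of Tph1 had 0.94. In svb9 the named probe of Rb1cc1 had a log2 ratio of 0.12 and that of Psmc3ip 0.13, and in old wild type -0.16 and -0.09. Creb3l4 had -0.43 in svb9 and -0.62 in old wild type, and Sh2d4a had -0.42 and -0.36, and 0 of these values passed the test. Ang4, an antimicrobial ribonuclease gene, and Ly6c1, a surface protein gene, are named after their values were seen, because a probe other than their brightest passed the test. That probe of Ang4 rose by 1.42 on the log2 scale and that of Ly6c1 by 1.21. In svb9 they had -0.29 and 0.50, and in old wild type 1.06 (adjusted p = 0.0763) and 0.37, none of which passed. Both belong to families of similar genes, so which member each probe read is uncertain.

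The limma test called 14 of 27860 probes in fl26, of which 6 were higher and 8 lower. At an unadjusted p under 0.05 there were 2833 probes, against 1393 by chance. With extraction date as a term, which leaves little information per probe to estimate the spread, the count was 121. Of these, 61 were higher and 60 lower, and all 14 probes were among them. Leaving out fl26 array 2 left 1 call, and leaving out fl26 array 1, either svb9 array or either old array left 0. All arrays share 1 estimate of the spread, so leaving out an array of another group changes the test and not the fl26 ratios. With median centring, with only the fl26 arrays or against a 1.5-fold change the count was 0, without background correction 2, with the strict filter 3 and with the Feature Extraction log ratios 6. It was 63 with a trend in the variance, 62 with a robust trend and 1001 (519 higher, 482 lower, all 14 among them) with the replicate number as a block.

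**Figure D1:**
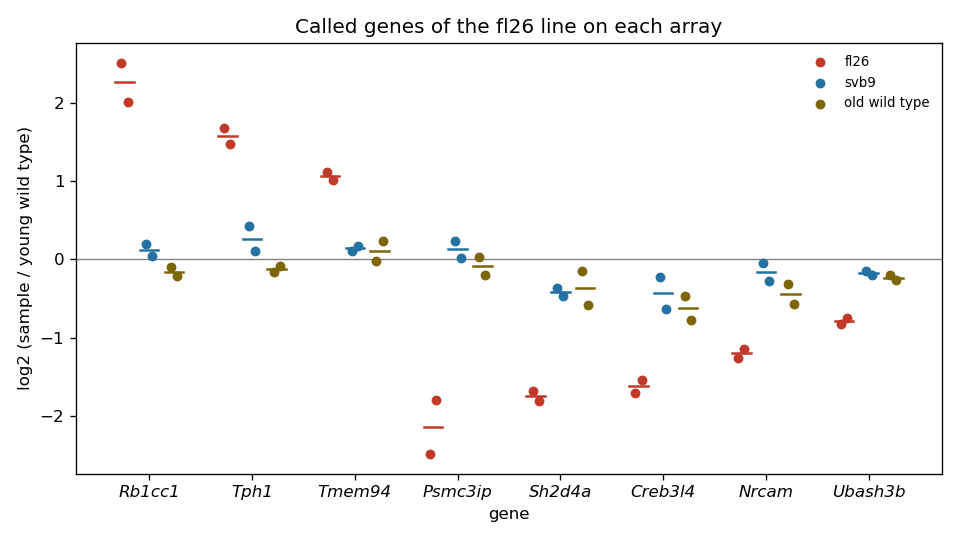
Log2 ratio over young wild type (y axis) of the 8 genes called in fl26 that met the naming rule (x axis), with 1 point per array and a line at the mean of the 2 arrays. The fl26 arrays of Rb1cc1 lie at 2.51 and 2.01, and those of Psmc3ip at -2.49 and -1.79, whereas their svb9 and old wild type arrays lie between -0.21 and 0.23.

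The fibroblast, macrophage, chemokine, basal and endothelial lists shifted up in fl26 and the interferon response list shifted down. Fibroblast and matrix genes had a median log2 ratio of 0.21, with 31 of 34 members higher (camera adjusted p = 7.44e-07; adjusted p = 0.623 with an estimated correlation). Macrophage markers had a median of 0.16, with 26 of 28 members higher (adjusted p = 1.58e-06; adjusted p = 0.623 with an estimated correlation). Chemokines, cytokines and secreted factors of senescence had a median of 0.12, with 36 of 42 higher (adjusted p = 6.89e-05; adjusted p = 0.623 with an estimated correlation). The short names chemokine list, chemokine genes and chemokines stand for this whole list and not for chemokines alone. Interferon response genes had a median of -0.16, with 25 of 33 lower (adjusted p = 0.000323; adjusted p = 0.623 with an estimated correlation). Basal epithelial markers had a median of 0.05, with 16 of 26 higher (adjusted p = 0.0207; adjusted p = 0.623 with an estimated correlation). Endothelial markers had a median of 0.07, with 16 of 22 higher (adjusted p = 0.0238; adjusted p = 0.623 with an estimated correlation).

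On the brightest probe of each gene, limma called 0 members of these 6 lists over all genes. When adjusted over the list alone, 9 interferon genes, 4 genes of the chemokine list, 3 fibroblast genes, 2 macrophage genes, 2 basal genes and 0 endothelial genes passed. Among the basal markers, the log2 ratios were 0.94 ± 0.11 for Col17a1, a hemidesmosome collagen gene, and 0.82 ± 0.08 for Trp63, the transcription factor of basal cells. Trp63 had an adjusted p of 0.0589, which was 0.0427 with date as a term and 0.00920 to 0.9998 over the alternatives. The largest fibroblast values were 0.60 for Ogn, 0.53 for Fbn1, 0.51 for Lum and 0.50 for Fbln2, and the largest macrophage values were 0.91 for Lyz1, 0.79 for Lyz2, 0.57 for Trem2 and 0.30 for C1qc. The endothelial list had 0.95 for Ly6c1, 0.80 for Lyve1, 0.41 for Egfl7 and 0.38 for Cd93. In the chemokine list, Angptl4 had 0.74, the protease inhibitor gene Timp3 0.71, Plat 0.58 and Igfbp2 -0.53. The interferon-induced genes Rtp4, Oasl2, Ifi44 and Ifit1 had -1.07, -0.84, -0.80 and -0.75. Second probes were lower for Col17a1 (0.14), Fbn1 (0.15), Lyz2 (0.23), Trem2 (0.17), Cd93 (0.0058) and Plat (0.18), and higher for Ly6c1 (1.21). With the replicate number as a block, Trp63, Col17a1, Ogn, Lyz1, Trem2, Ly6c1, Egfl7, Angptl4, Timp3, Plat, Igfbp2, Rtp4 and Oasl2 were called. With date as a term, Col17a1, Timp3, Lyve1 and Lyz2 were called besides Trp63 (limma adjusted p = 0.0354, 0.0333, 0.0369 and 0.0419 for these).

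For the 5 raised lists the median on fl26 array 2 was at most 0.05. The fibroblast median was 0.44 on array 1 and -0.03 on array 2, the macrophage median 0.25 and 0.05, and the chemokine median 0.21 and 0.04. The basal median was 0.17 and -0.02, the endothelial median 0.21 and -0.01, and the interferon median -0.26 and -0.12. Without fl26 array 1, 1 list was called in fl26 and it was none of these 6; without fl26 array 2, 11 lists were called. Without fl26 array 1 the adjusted p was 0.722 for fibroblast genes, 0.391 for macrophage markers, 0.576 for chemokines and 0.576 for interferon genes. It was 0.611 for basal markers and 0.879, with the direction reversed, for endothelial markers. Erythrocyte genes, a sign of blood in the tissue, had a median of 0.29 on fl26 array 1 and 0.01 on array 2. With date as a term the basal and endothelial lists had an adjusted p of 0.105 each, with medians of 0.050 and 0.054 against 0.049 and 0.069 without it. The mitochondrial respiratory chain list was then called as lower (adjusted p = 0.00676; 0.00851 with the replicate block; adjusted p = 0.623 with an estimated correlation). Each date held at most 1 fl26 array, so the array values are also the within-date values.

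Lists of lipid enzymes, growth, senescence and androgen response did not pass. Lipoxygenase and prostanoid enzymes had a median log2 ratio of 0.00 (11 of 22 higher, adjusted p = 0.938). Senescence and cell cycle inhibitors had -0.02 (adjusted p = 0.326), proliferation genes 0.03 (adjusted p = 0.0693), PPAR and fatty acid oxidation genes -0.00 (adjusted p = 0.842), androgen response genes 0.01 (adjusted p = 0.623) and luminal epithelial markers -0.07 (adjusted p = 0.443). The 25 lists that were not called had adjusted p from 0.0693 to 0.940. Among single genes, the log2 ratio was -0.24 for Cdkn1a, 0.25 for Mki67, 0.14 for Pbsn and -0.01 for Alox15. It was 0.27 for Krt5, 0.23 for Krt14, -0.04 for Krt8 and -0.21 for Krt18. Of these 8 genes, 0 passed the limma test. Red signal of Cdkn1a and of Alox15 was well above background on 1 fl26 array each. The red signal of Krt18 and of Pbsn was saturated on 1 fl26 array, and the other array gave -0.10 for Krt18 and 0.95 for Pbsn. Smooth muscle markers had a median of -0.02 (adjusted p = 0.666), T and NK cell markers 0.02 (0.940) and B and plasma cell markers 0.0075 (0.770). The mouse probe for Alox15b was well above background on 1 array, in green only, and that for Cdkn2a on 0, so neither was tested. No probe carried the name Alox5. The level of the transgene itself was not tested.

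**Figure D2:**
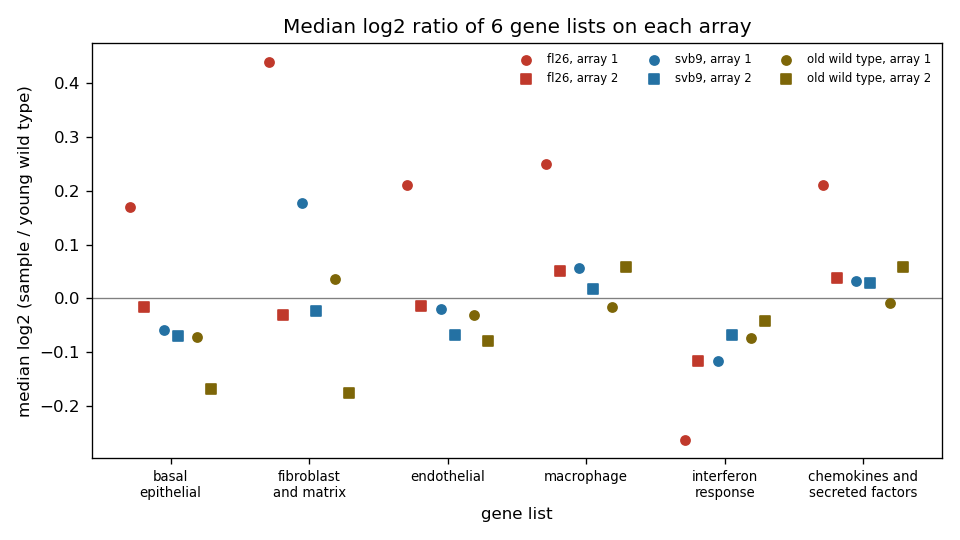
Median log2 ratio over young wild type (y axis) of the 6 gene lists called in fl26 (x axis), on each of the 6 arrays, with circles for array 1 and squares for array 2 of each group. The fibroblast median is 0.44 on fl26 array 1 and -0.03 on fl26 array 2.

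The second comparison asked which genes differ between the svb9 line and young wild type. No gene passed in the limma test, and the 5 that the rule named had an adjusted p of 0.980 each. Dock11, which encodes an activator of a small GTPase, had a log2 ratio of -0.999 ± 0.11 (n = 2) and Krt23, a keratin gene, had -0.46 ± 0.07. Colgalt1, a collagen-modifying enzyme gene, had 0.98 ± 0.14, Fgl1, a secreted protein gene, had 0.61 ± 0.09 and Slc25a46, a mitochondrial carrier gene, had 0.51 ± 0.07. Other probes gave -0.07 for Fgl1, -0.52 for Dock11, and 0.0037 and 0.031 for Slc25a46. Limma called 0 of 27860 probes, with 1240 at an unadjusted p under 0.05 against 1393 by chance, and 0 with date as a term. With the replicate number as a block it called 12 (10 higher, 2 lower), Dock11 among them.

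No gene list was called in svb9. The fibroblast list had a median log2 ratio of 0.04, with 20 of 34 members higher (adjusted p = 0.0610), and 0.18 on array 1 against -0.02 on array 2. The interferon list had a median of -0.15, with 21 of 33 members lower (adjusted p = 0.0610), and -0.12 and -0.07 on the arrays. The senescence list had a median of -0.00 (adjusted p = 0.953), the proliferation list -0.05 (adjusted p = 0.187) and the lipoxygenase list -0.01 (adjusted p = 0.771). Adjusted over the list alone, 0 fibroblast genes and 0 interferon genes passed. The replicate block called the interferon and the mitochondrial respiratory chain lists as lower (adjusted p = 0.0274 each; adjusted p = 0.864 each with an estimated correlation). Without svb9 array 1, 1 list was called, without svb9 array 2 it was 5, and without either fl26 array or either old array it was 2. Trp63 had 0.08, Krt5 -0.05, Krt14 -0.12, Krt8 -0.06, Krt18 -0.23, Pbsn -0.04, Mki67 -0.24, Cdkn1a -0.06 and Alox15 -0.06, and none of these 9 passed the test. The 2 svb9 arrays lay far apart for Pbsn (-1.34 and 1.26) and for Mki67 (0.050 and -0.52), so their means do not show an unchanged level. Krt18 was saturated in red on 1 svb9 array, and the other array gave -0.17. Red signal of Mki67, Cdkn1a and Alox15 was well above background on 1 svb9 array each.

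The third comparison asked which genes differ between old and young wild type. Stra6, which encodes a receptor for vitamin A uptake, had a log2 ratio of 1.65 ± 0.12 (n = 2, adjusted p = 0.0599) and did not pass, although it did with date as a term (adjusted p = 0.0373; 0.00309 to 0.281 over the alternatives). Sf3b2, a splicing factor gene, had 0.93 ± 0.07, Zfp932, a zinc finger gene, had 0.81 ± 0.07 and G3bp1, a stress granule gene, had 0.72 ± 0.07, with 0.18 on its second probe. Magt1, which encodes a magnesium transporter, had -0.94 ± 0.09, with red signal well above background on 1 array. All had the same sign on both arrays, as the rule required, and an adjusted p of 0.0599 to 0.0607. All 5 were called with the replicate number as a block. Median centring turned the sign of Stra6 to -1.18, of Sf3b2 to -1.84, of Zfp932 to -2.15 and of G3bp1 to -1.49. That setting moved the array medians to between -0.45 and 0.35.

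Limma called 0 of 27626 probes in old wild type, with 3158 at an unadjusted p under 0.05 against 1381 by chance. With date as a term it called 11, all higher, and 6 gene lists. Skeletal muscle (median -0.15), interferon (-0.11) and proliferation genes (-0.080) were added as lower, and macrophage (0.078) and chemokine genes (0.062) as higher, each with an adjusted p of 0.817 or more with an estimated correlation. The replicate block called 1211 probes (731 higher, 480 lower). The count was 175 with a trend in the variance, 205 with a robust trend, 62 with the strict filter, 53 with only the old arrays, 32 with outlier spots kept and 4 with 1 value per gene. Leaving out fl26 array 1 or fl26 array 2 gave 2 calls each. At least 2-fold on both arrays were 32 probes, all higher, against 35 in fl26 (20 higher, 15 lower) and 0 in svb9. These counts depend on the processing: with the Feature Extraction log ratios they were 518 in old wild type, 125 in fl26 and 6 in svb9. In old wild type the count was 129 with outlier spots kept and 3721, all lower, with median centring, which gave 3 in svb9. In fl26 it was 11 with the strict filter. Large falls could hardly be seen in old wild type, where 3205 tested probes had red signal well above background on both arrays.

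The ventral prostate secretory products were the 1 list called in old wild type. Of its 9 measured members 7 were higher, with a median log2 ratio of 0.45 (adjusted p = 0.00418; adjusted p = 0.817 with an estimated correlation). When adjusted over the list alone 4 members passed (Ang, Mt3, Sbp and Spink1), against 0 over all genes. The log2 ratio was 1.34 ± 0.17 for Ang, a ribonuclease gene, and 0.54 ± 0.18 for Mt3, a metal-binding protein gene, and both were called over all genes with the replicate block. Red signal of Mt3 was well above background on 1 old array. Sbp, the spermine-binding protein gene, and Spink1, a trypsin inhibitor gene, were saturated in the green channel on both old arrays, so no fold is given. The second probe of Spink1 went the other way (log2 ratio -0.11), whereas that of Sbp had the same direction. With saturated spots missing the list had a median of 0.17 and was not called (adjusted p = 0.181), and it was not called without old array 1 (adjusted p = 0.0730) or with median centring, which reversed it (adjusted p = 0.664). The lists of senescence (median -0.10, adjusted p = 0.207), proliferation (-0.06, 0.175), luminal (0.12, 0.183) and basal markers (-0.08, 0.347) did not pass. Without old array 1, 3 lists were called, and without old array 2 it was 2.

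In old wild type, the log2 ratio was 0.29 for Trp63, -0.22 for Krt5 and -0.17 for Krt14, and 0 of these passed. Their red signal was well above background on 1 old array each. Krt8 (0.51), Krt18 (0.75) and Pbsn (0.56) had a value on 1 array each. The replicate block called Krt18 and turned Pbsn to -0.50. Red signal was not well above background on either old array for Mki67, Cdkn1a and Alox15, so no change is given for them. Median centring reversed Trp63 to -1.13, Krt8 to -4.64, Krt18 to -1.22 and Pbsn to -1.45.

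The fourth comparison set fl26 against svb9, in which the dyes cancel. No gene passed, and the rule named the 5 with the smallest p that met its conditions. Rb1cc1 differed by 2.14 ± 0.18 on the log2 scale (adjusted p = 0.220), Psmc3ip by -2.27 ± 0.24, Ang4 by 1.82 ± 0.18, Tph1 by 1.31 ± 0.15 and Gabra4, a GABA receptor gene, by 1.07 ± 0.12 (adjusted p = 0.355 each). That both fl26 arrays lay beyond both svb9 arrays for these 5 genes was a condition of the rule. Limma called 0 of 27860 probes, with 607 at an unadjusted p under 0.05 against 1393 by chance. With date as a term it called 2, both lower in fl26, and the separate-channel fit called 33. The replicate block called 10 (8 higher, 2 lower), among them Rb1cc1, Psmc3ip, Tph1 and Gabra4.

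By the list test, 8 lists differed between the lines, and all 8 had an adjusted p of 0.884 with an estimated correlation. Macrophage markers were higher in fl26 by a median log2 of 0.11 (26 of 28 members, adjusted p = 9.52e-06), basal markers by 0.09 (22 of 26, adjusted p = 1.9e-05) and proliferation genes by 0.10 (38 of 50, adjusted p = 2.82e-05). Endothelial markers were higher by 0.11 (21 of 22, adjusted p = 0.000252), fibroblast genes by 0.14 (30 of 34, adjusted p = 0.000286), cholesterol and fatty acid synthesis genes by 0.12 (19 of 22, adjusted p = 0.00148) and chemokines by 0.08 (36 of 42, adjusted p = 0.00172). Interferon response genes were lower by a median of -0.09 (23 of 33, adjusted p = 0.0425). Adjusted over the list alone, 2 basal genes and 1 chemokine gene passed, and 0 in the other 6 lists, against 0 over all genes.

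Among members, the difference was 0.85 for Col17a1, 0.74 for Trp63, 0.36 for Krt14 and -0.44 for Krt6a in the basal list. It was 0.70 for Lyz1, 0.61 for Lyz2, 0.51 for Trem2 and 0.42 for C1qc in the macrophage list. It was 0.49 for Mki67, 0.42 for Cdc20, 0.38 for Gmnn and 0.37 for Cdt1 in the proliferation list. On array 1, extracted on the same date for both lines, Mki67 was not higher in fl26 (-0.0013) than in svb9 (0.050). Neither was Cdc20 (0.023 and 0.092), whereas Gmnn (0.39 and 0.056) and Cdt1 (-0.046 and -0.29) were higher in fl26 there. With date as a term the difference was 0.22 for Mki67, 0.15 for Cdc20 and 0.28 each for Gmnn and Cdt1. Fdps, Dhcr7, Fdft1 and Sqle of sterol synthesis differed by 0.58, 0.36, 0.35 and 0.26. Fbln2 differed by 0.78, Col1a1 and Lum by 0.40 each and Serpinf1 by 0.38, Ly6c1 by 0.77, Lyve1 by 0.64, Cd93 by 0.49 and Ptprb by 0.44. Igfbp2 differed by -0.98, Cxcl17 by 0.56, Timp3 by 0.54 and Cxcl15 by 0.40, and Oas1a, Ifi44, Usp18 and Rtp4 by -0.63, -0.61, -0.58 and -0.51. None of these members was called. Second probes differed by less, with 0.16 for Col17a1 and for Lyz2, 0.14 for Trem2 and 0.0022 for Cd93. They gave 0.11 for Mki67, 0.046 for Fdps, -0.015 for Dhcr7, 0.10 for Serpinf1 and 0.70 for Ly6c1. The 2 other probes of Col1a1 differed by 0.085 and 0.12.

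On the first date, which held array 1 of both lines, the within-date medians were 0.22 for macrophage, 0.22 for basal, 0.05 for proliferation, 0.26 for endothelial, 0.27 for fibroblast, 0.14 for cholesterol, 0.16 for chemokine and -0.20 for interferon genes. Cholesterol genes were not called with date as a term (median 0.072, adjusted p = 0.163). That fit called smooth muscle markers as lower (median -0.17, adjusted p = 0.00166) and erythrocyte genes as higher (median 0.18, adjusted p = 0.0333), each with an adjusted p of 0.884 with an estimated correlation. Over the alternatives other than left-out arrays the highest adjusted p was 0.910 for each of the 8 lists, and the lowest lay between 7.14e-09 for macrophage and 0.000847 for interferon genes. Without fl26 array 1 the adjusted p was 0.607 for macrophage, 0.460 for basal, 0.788 for endothelial and 0.460 for cholesterol genes. It was then 0.779 for chemokines, and 0.646 for fibroblast and 0.690 for interferon genes with the direction reversed. Proliferation genes were lost without fl26 array 2 (adjusted p = 0.239). Without svb9 array 2, cholesterol (0.123), fibroblast (0.123) and interferon genes (0.481) were not called, and chemokines were not without svb9 array 1 (0.104). Interferon genes were also not called without old array 1 (0.0816) or old array 2 (0.0518).

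Both transgenic lines were also set against old wild type, which combines the line with an age difference. Fibroblast and matrix genes were higher in fl26 than in old wild type by a median log2 of 0.34 (31 of 34 members, adjusted p = 1.85e-08; adjusted p = 0.718 with an estimated correlation), although the within-date median was -0.03. Proliferation genes were higher by 0.11, basal markers by 0.10, endothelial markers by 0.19 and macrophage markers by 0.09 (adjusted p = 0.00168, 0.0018, 0.00733 and 0.00871). With an estimated correlation the adjusted p was 0.718, 0.718, 0.777 and 0.777 for these 4. Interferon genes were lower by a median of -0.15, luminal markers by -0.10 and ventral prostate secretory products by -0.31 (adjusted p = 0.00871, 0.0355 and 0.0422; adjusted p = 0.718 each with an estimated correlation), and median centring reversed these 3. With saturated spots missing, secretory products had a median of -0.082 and were not called (adjusted p = 0.629). Adjusted over the list alone, 4 fibroblast, 6 basal, 4 luminal and 1 interferon gene passed, against 0 over all genes.

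Limma called 0 probes between fl26 and old wild type (2138 at an unadjusted p under 0.05; 5 calls with date as a term; 25 with the replicate block; 773 by the separate-channel fit). Without fl26 array 1, 1 list was called, that of proliferation genes. The adjusted p was then 0.148 for fibroblast, 0.162 for basal, 0.717 for endothelial, 0.717 for macrophage, 0.785 for interferon and 0.148 for luminal genes and 0.495 for secretory products. Without fl26 array 2, proliferation (adjusted p = 0.192) and luminal genes (0.0763) were lost, without old array 1 macrophage (0.228) and interferon genes (0.163), and without old array 2 basal (0.113), endothelial (0.0695) and proliferation genes (0.102). The fit with date called 4 lists and added skeletal muscle markers as higher (median 0.13, adjusted p = 0.0033; adjusted p = 0.873 with an estimated correlation). It lost endothelial (0.0818), macrophage (0.0788), interferon (0.233) and luminal genes (0.216) and secretory products (0.352), with medians of 0.10, 0.025, -0.11, -0.15 and -0.11. Over the alternatives other than left-out arrays the adjusted p of the 8 lists ranged from 3.66e-11 to 0.777. The within-date medians were 0.09 for proliferation, 0.08 for basal, 0.01 for endothelial, 0.07 for macrophage, -0.14 for interferon, -0.09 for luminal genes and -0.19 for secretory products.

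Between svb9 and old wild type, fibroblast genes were higher in svb9 by a median log2 of 0.16 (27 of 34, adjusted p = 0.000517) and smooth muscle markers by 0.18 (12 of 16, adjusted p = 0.0405), each with an adjusted p of 0.922 with an estimated correlation. Ventral prostate secretory products (median -0.19, 7 of 9 lower, adjusted p = 0.0135) and luminal markers (median -0.15, 13 of 18 lower, adjusted p = 0.0206) were lower (adjusted p = 0.922 each with an estimated correlation), and median centring reversed both. With saturated spots missing, secretory products (median -0.095, adjusted p = 0.495) and smooth muscle markers (median 0.18, adjusted p = 0.0538) were not called. The within-date medians were 0.12, 0.36, -0.33 and -0.23. Limma called 0 probes (1301 at an unadjusted p under 0.05; 0 with date as a term; 31 by the separate-channel fit). Adjusted over the list alone, 1 secretory gene passed. Without svb9 array 1, 1 list was called and it was none of these 4 (adjusted p = 0.0836 for fibroblast and for smooth muscle, 0.135 for luminal and 0.410 for secretory genes). Without svb9 array 2, luminal (0.137) and smooth muscle markers (0.151) were lost, without old array 2 fibroblast genes (0.306) and smooth muscle markers (0.875), and without old array 1 luminal markers (0.0511). The fit with date called 2 lists and added skeletal muscle markers as higher (median 0.21, adjusted p = 1.43e-05; adjusted p = 0.922 with an estimated correlation). It lost fibroblast genes (0.427), luminal markers (0.0503) and secretory products (0.229), with medians of -0.026, -0.21 and -0.086. Over the alternatives other than left-out arrays the adjusted p of the 4 lists ranged from 1.65e-05 to 0.962.

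Across 27546 probes, which are not independent replicates, the mean log2 ratios of fl26 and svb9 correlated with r = 0.62. Unchanged groups against shared young wild type pools, simulated 20 times, gave r = 0.50, with a covariance of 0.0070 against 0.0169 observed. The value was 0.33 for fl26 and old wild type (covariance 0.0125) and 0.45 for svb9 and old wild type (covariance 0.0127), with a simulated r of 0.50 for each. The simulation assumed that arrays with the same number share a pool, which the files do not state. It held no probe-specific dye effect, which all arrays would share because the dyes were never swapped, and which would raise the observed values. A covariance above the simulated one therefore does not show that the groups moved alike. Median centring turned the fl26 and old value to -0.38, and that for svb9 and old wild type to 0.11. Without svb9 array 2 the latter was 0.09 and without old array 2 it was 0.20. Without fl26 array 2 the value was 0.32 for fl26 and svb9 and 0.03 for fl26 and old wild type, and without old array 2 the latter was 0.09. Without svb9 array 2 the fl26 and svb9 value was 0.36.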

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

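The tests of tissue makeup, luminal share, extraction date, a common young wild type pool and probe sequence were chosen after the results they bear on had been seen. The tests of noise near background and of neighbouring genes were chosen before, but how to read a count on the bound of the latter was set after its count was seen.

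The list test of fl26 against svb9 set 8 lists apart, because the difference between the lines itself passed the threshold, although none of the 8 was called with an estimated correlation (adjusted p = 0.884). The median log2 difference was 0.14 for fibroblast and matrix genes, 0.11 for endothelial markers, 0.11 for macrophage markers, 0.077 for chemokines, cytokines and secreted factors of senescence and 0.094 for basal epithelial markers. It was 0.12 for cholesterol and fatty acid synthesis genes, 0.10 for proliferation genes and -0.090 for interferon response genes.

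The first pattern is the higher level of the fibroblast, macrophage, endothelial, chemokine and basal lists in fl26. The chemokine list also holds cytokines and secreted factors of senescence. The fibroblast median was also higher on array 1 than on array 2 in svb9 (0.18 and -0.02) and in old wild type (0.04 and -0.17). In old wild type the macrophage (-0.02 and 0.06) and chemokine medians (-0.01 and 0.06) went the other way. Part of the fibroblast shift may thus follow the array number, which was not tested. A lower share of luminal epithelium would raise the other cell types alike only if these kept their proportions. On fl26 array 1 the fibroblast median was 0.44 (34 genes), the smooth muscle median 0.07 (16 genes) and the luminal median 0.0004. The fibroblast and smooth muscle medians differed by 0.37 (1-sided permutation of the members, p = 1e-05, the smallest that 100000 permutations can give). That permutation takes genes of 1 array as independent, and cell types may not rise alike, so a lower luminal share stays open. Extraction date as the whole cause is argued against by the within-date fibroblast difference of 0.27 between fl26 array 1 and svb9 array 1, although that between fl26 array 2 and old array 1 was -0.03. The makeup of the tissue in 1 fl26 pool cannot be told apart from other differences between the 2 arrays: 0 of 5 lists had a median on array 2 of at least 1/3 of that on array 1, but these medians prompted the question. The transgene and a change within the stroma stay open and untested, and single genes such as Lyz1 (1.06 and 0.77) and Trp63 (0.78 and 0.86) were high on both arrays.

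The second pattern is that 4 of 6 pairs of arrays with the same number had alike log ratios across groups (r = 0.47 to 0.68), whereas fl26 array 1 and svb9 array 1 had r = -0.024 and -0.035 with old array 1. Extraction date as the whole cause is argued against: the highest correlation among pairs of different dates was 0.68, against 0.14 to 0.56 for the pairs extracted on 1 date. Noise of spots near background is argued against: among 3192 probes bright on all arrays, the 4 pairs had r = 0.58 to 0.76 and the other 2 had -0.12 and -0.16, and the mean of all 6 was 0.39 against 0.20 for different-number pairs, a difference of 0.19. A young wild type pool common to the arrays of 1 number cannot be told apart from other causes: the green channels of 4 of 6 same-number pairs correlated more than every different-number pair (highest 0.993), and the pairs with old array 1 did not (lowest 0.990). Red signal also sorted the arrays: array 1 of fl26 and svb9 had 27151 and 27833 probes well above background. Array 2 of fl26, svb9 and old wild type had 17623, 14620 and 13600, and old array 1 had 3219. The 4 alike pairs join arrays of similar red signal, so signal strength cannot be told apart from the number and was not tested. No biological explanation was tested, since the labels give the numbers no meaning.

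The third pattern is single genes far from young wild type in fl26. Probe sequence in place of gene level is argued against for Psmc3ip and Tph1, since 2 of 2 other probes had at least 0.5 of the log2 ratio, in the same direction. It stays open for Rb1cc1, where 1 of 4 other probes did, and for Ang4 and Ly6c1, where 2 of 2 did but may read similar genes of the same families. A changed stretch of chromosome beside the transgene cannot be told apart from chance: the 100 genes with the smallest p held 22 pairs within 2 Mb of each other, and 6.98% of 10000 random sets (mean 14.9) held as many. The count equals the 95th percentile of those sets, which was first read as arguing against this explanation and is left open because it does not lie inside the bound by more than its spread; the transgene stays untested.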

How the results depend on the processing

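Treating saturated spots as missing was chosen after the data were seen. The files' signal over background limits the old group most, with 3219 red probes well above background on its array 1. The 8 genes named as called in fl26 kept their sign under every setting that tested them (the strict filter tested 1 of them); they stayed called with quantile normalization between arrays, no filter, a trend in the variance, both blocks and saturated spots missing. Over the alternatives their adjusted p ranged from 0.000866 to 0.9998. All 27 called lists kept their call with array weights and the replicate block, and with quantile normalization, which leaves the log ratios as they were. For genes with values on all arrays, the replicate block leaves the group means as they were and changes only the spread. Over the alternatives other than left-out arrays, the adjusted p ranged from 2.18e-08 to 0.623 for fibroblast genes, from 1.31e-07 to 0.623 for macrophage markers, from 2.4e-05 to 0.892 for chemokines and from 3.75e-05 to 0.623 for interferon genes in fl26. It ranged from 0.0109 to 0.623 for basal and from 0.0106 to 0.623 for endothelial markers in fl26, and from 9.13e-06 to 0.817 for secretory products in old wild type. The cause of each change below was not tested unless stated.

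Camera with an estimated correlation and fry called 0 lists in fl26, old wild type, fl26 against svb9, fl26 against old and svb9 against old, against 6, 1, 8, 8 and 4. Without background correction, 2 probes were called in fl26 and 2 lists in svb9; Alox15 in fl26 turned to 0.0028 and Pbsn in svb9 to 0.056. With the Feature Extraction log ratios and with the series table alike, 6 probes were called in fl26, 125, 6 and 518 probes were 2-fold on both arrays in fl26, svb9 and old wild type, 5 lists were called in fl26 against old, and Krt8 in old wild type was -0.30.

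Median centring moved the array medians to between -0.45 and 0.35. It called 0 probes in fl26, and gave 3 probes 2-fold on both arrays in svb9 and 3721 in old wild type. The correlation of fl26 and old was -0.38 and that of svb9 and old 0.11. It called 14 lists in old wild type, 13 in fl26 against old and 10 in svb9 against old. It reversed the secretory products in old wild type (adjusted p = 0.664), fl26 against old (0.396) and svb9 against old (0.786), luminal markers in fl26 against old (0.0132) and svb9 against old (0.0106), and interferon genes in fl26 against old (0.680). In fl26 it turned Krt8 to 0.29 and Krt18 to 0.14. In old wild type it turned Pbsn to -1.45, Trp63 to -1.13, Krt8 to -4.64, Krt18 to -1.22, Stra6 to -1.18, Sf3b2 to -1.84, Zfp932 to -2.15, G3bp1 to -1.49, Ang to -0.13 and Mt3 to -0.75, and the saturated Sbp to -0.50 and Spink1 to -1.11.

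With the strict filter, which tests fewer probes, 3 probes were called in fl26 and 62 in old wild type, 11 probes were 2-fold in fl26, and 0 lists were called in fl26, fl26 against svb9 and fl26 against old and 1 in svb9 against old. Chemokines in fl26 against svb9 reversed (adjusted p = 0.437). With flagged spots kept, 32 probes were called and 129 were 2-fold in old wild type, and 1, 3, 13 and 7 lists were called in svb9, old wild type, fl26 against old and svb9 against old. With a trend, 63 probes were called in fl26, 175 in old wild type, 4 in fl26 against svb9 and 2 in fl26 against old; with a robust trend it was 62, 205, 4 and 2. Both called 1 list in svb9 and 2 in svb9 against old. With only the arrays of the groups compared, 0 probes were called in fl26 and 53 in old wild type, and 3 lists in svb9. The test against a 1.5-fold change called 0 probes in fl26. With 1 value per gene, 4 were called in old wild type. With saturated spots missing, 0 lists were called in old wild type and 2 in svb9 against old. The separate-channel fit called 33, 773 and 31 probes in fl26 against svb9, fl26 against old and svb9 against old.

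With date as a term, 121 probes were called in fl26, 11 in old wild type, 2 in fl26 against svb9 and 5 in fl26 against old, and 6, 4 and 2 lists in old wild type, fl26 against old and svb9 against old. It turned Pbsn in svb9 to 0.070 and in old wild type to -0.63, and Krt8 in svb9 to 0.055. Among named genes it added calls for 6: Trp63, Col17a1, Timp3, Lyve1 and Lyz2 in fl26 and Stra6 in old wild type.

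The labels give the 2 replicate numbers no pairing, and 2 of the 6 same-number pairs of arrays also share an extraction date. With the replicate block, 1001 probes were called in fl26, 12 in svb9, 1211 in old wild type, 10 in fl26 against svb9 and 25 in fl26 against old, and 2 lists in svb9. Apart from the lists and named genes given with each comparison it changed no other call of a list or named gene. It turned Pbsn in old wild type to -0.50.

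Leaving out each array in turn, with the lone array of a group assumed to vary like the others, gave 0 to 1 probes called in fl26, 0 to 2 in old wild type, and 1 to 11, 1 to 5, 1 to 3, 1 to 10, 1 to 9 and 1 to 4 lists in fl26, svb9, old wild type, fl26 against svb9, fl26 against old and svb9 against old. The correlation ranged from 0.32 to 0.62 for fl26 and svb9, from 0.028 to 0.43 for fl26 and old wild type and from 0.088 to 0.51 for svb9 and old wild type. The adjusted p of endothelial markers in fl26 ranged from 1.87e-07 to 0.879, that of fibroblast genes in fl26 against svb9 from 1.00e-13 to 0.646 and that of interferon genes there from 4.04e-08 to 0.690, each reversed without fl26 array 1. Log2 ratios that changed sign ranged, in fl26, from -0.67 to 0.95 for Pbsn, -0.16 to 0.078 for Krt8 and -0.0013 to 0.50 for Mki67. In svb9 they ranged from -0.16 to 0.044 for Alox15, -1.34 to 1.26 for Pbsn, -0.15 to 0.052 for Krt5, -0.15 to 0.038 for Krt8, -0.52 to 0.050 for Mki67 and -0.11 to 0.0012 for Cdkn1a. In fl26 against svb9 they ranged from -0.020 to 0.72 for Fdft1, -0.056 to 0.86 for Col1a1, -0.088 to 0.89 for Lum and -1.24 to 0.081 for Usp18. The count of probes 2-fold on both arrays cannot be had without an array of its group.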

Other observations

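The genes named in this part were chosen after the data were seen, and 0 of them passed the limma test. Ang, which encodes a secreted ribonuclease, had a log2 ratio of 1.36 in fl26 (adjusted p = 0.119), -0.28 in svb9 and 1.34 in old wild type (adjusted p = 0.112). The difference of 1.64 for Ang between fl26 and svb9 did not pass (adjusted p = 0.597). Ang2 had 1.17, -0.12 and 0.66, and since both genes are alike in sequence, their probes are not independent.

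Clu, which encodes a secreted chaperone, had a log2 ratio of 2.62 on fl26 array 2 and 0.54 in svb9, with red saturated on fl26 array 1 and no value in old wild type. Psca, a surface protein gene of the prostate, had 1.44 in fl26 (1.33 and 1.56), 0.35 in svb9 and 0.76 in old wild type. H2-Q10, a gene of the major histocompatibility complex, had -2.56 and -2.07 in fl26 on 2 of its 5 probes and -0.32 to 0.00 on the other 3. The median of mitochondrial respiratory chain genes was -0.04 on fl26 array 1 and -0.26 on array 2 (adjusted p = 0.0693; 0.00676 with date as a term, 0.525 with fry and 0.623 with an estimated correlation).

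The log ratios of the 2 arrays of a group correlated across probes with r = 0.26 in fl26, 0.17 in svb9 and 0.39 in old wild type, and had the same sign for 53.4%, 55.5% and 57.8% of probes. The median, the mean and the test of a list differed in sign for 5 of 31 lists in fl26, 7 in svb9 and 5 in old wild type.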
